A study of Homo sapiens with 16 samples.

How the data were processed

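The series measured RNA in single cells of SK-N-AS, an established human neuroblastoma cell line without MYCN amplification, with MARS-seq, a 3' single-cell method in which cells are sorted singly into wells of a plate and each well gets its own barcode. The labels describe 16 samples. The deposited table holds 603 columns of cells and 27044 rows of genes, and its column names are barcodes that show no sample, so the cells were treated as 1 sample. No replicate exists at that level, and no comparison between the 16 samples was made.

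The deposited values are whole-number counts per gene and cell, not normalized, per the file itself, and whether they are molecules or reads is not given in the sources used here. The reads were aligned with Bowtie2 2.1.0 to hg19, per the submitters' processing notes. The counting tool, the gene annotation and the filter on cells are not given in the sources used here. All 603 columns were read as cells, which is also the number of single cells the labels state. The lowest total is 1000 counts, so the planned minimum of 500 counts per cell removed 0 cells. A row named unknown held 2 counts (0.00013% of all) and was left out of totals. No row carries a mitochondrial or ERCC name, so neither share was computed. Row names were matched to current and older gene symbols, and 484 rows were matched to members of the gene lists. Where a row joins several genes, its first symbol is printed and the joint row is named where it matters.

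The column names use 364 distinct barcodes, of which 239 occur in both a first run of 316 columns and a second run of 287. These are called barcode set 1 and barcode set 2. They were found from the file, are not groups of the study, and served only as a check, with values given within each set beside the pooled one. No doublet caller was run because the labels describe single cells sorted into wells. The deepest cell was left out as an alternative.

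Gene levels are CPM, that is counts summed over all cells and scaled to the usual fixed library total, with exact Poisson intervals at 95%. Shares of cells carry exact Clopper-Pearson binomial intervals at 95%. All intervals and limits cover counting error only, not differences between cells, plates or cultures. A gene at 0 is given a 1-sided 95% limit of 3 counts, which is 1.95 CPM or 0.498% of cells with a count. The upper end of a 2-sided interval would lie somewhat higher. Before the data were examined, 28 gene lists were fixed from textbook knowledge, covering the mesenchymal and adrenergic states of neuroblastoma, cell types and cell programs. A list's level is the median over members of log2(CPM + 1). Its interval comes from 1000 Poisson redraws of the counts. Its percentile is the share of 10000 random lists of the same size with a lower median, drawn from the 18660 rows that match protein-coding genes and hold 97.9% of the counts.

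For values per cell, each cell was thinned without replacement to 1100 counts, which left out 43 shallower cells (7.13%) and kept 560. A cell's score for a list is its thinned count over the list. For each of 3 lists, the 186 cells with the highest and the 186 with the lowest score were summed with their full counts, and log2 ratios of CPM were taken with exact conditional binomial intervals. Genes of the scored list were left out of every other list in that comparison. List ratios given without certain members were chosen after the values were seen. Groups cut from a score are ranges of cells, not types. With 1 sample there was no test, and no p-value or count of changed genes was made. The planned count model across samples was not used for the same reason, and neither edgeR nor DESeq2 was run.

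The rule for named genes was fixed before the data were examined. It names the 10 genes with the highest CPM outside the ribosomal protein genes, the 4 members of each list with the highest CPM, members of the state and cell type lists at 0, and the 20 genes with the most cell-to-cell variation. For each score comparison it names the 15 genes with the highest and the 10 with the lowest log2 ratio, among genes outside the scored list with at least 50 counts in all cells. These are the extremes of all the ratios, and the interval of a named gene does not allow for that choice. A few genes that the rule names are not reported here, though list values include them. Any other gene is named because it belongs to a fixed list or was chosen after its values were seen, which is said there.

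Covariation of a list is the mean Spearman rho over pairs of its members across the 560 thinned cells, set against 10000 random lists matched on mean among 4041 genes. Correlations between list scores use Pearson's r and Spearman's rho, after removing shared members. Cell-to-cell variation is the Fano factor (variance over mean of thinned counts) of genes with a mean of at least 0.1, ranked by its excess over the running median of genes of like mean. Clusters were found with scanpy on log-transformed counts per 10000, 2000 variable genes, 20 principal components, 15 neighbours and Leiden at resolution 0.5. A cluster was to be named only with at least 3 fixed cell type markers among its leading genes.

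Each method was tested on simulated data drawn from the real genes' means and the real cells' totals. For the 3 score comparisons, 1 in 3 simulated cells had the whole scored list raised 4-fold. That is a sharper split than in the real cells, many of which lie at the bounds of the groups. The simulation thus does not show how well the real groups are separated. In it, genes set to 4-fold came out at a median log2 of 1.82 (G2M score, 4599 genes), 1.84 (G1/S score, 4611 genes) and 1.85 (mesenchymal score, 4620 genes). Genes set to 2-fold came out at 0.92, 0.85 and 0.84, and unchanged genes at a median of -0.12, -0.12 and -0.16, since the raised genes take counts from the rest. In the real comparisons the median over all these genes was 0.010, 0.021 and 0.012. For variation, 91% of 200 varied genes were recovered among 2104 genes. The varied genes were drawn from the more abundant genes only. This recovery therefore does not cover sparse genes near the bound of 0.1, such as CHGA and GCG (thinned means of 0.118 each). A planted covarying list reached percentile 100 and 0 of 20 other lists lay above the middle 95% of random lists. In clustering, 97.3% of a planted population fell in 1 of 3 clusters, and simulated cells without any structure still gave 2 clusters.

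Alternatives covered the way a list's members are averaged, the score groups, the thinned depth, the clustering settings and, chosen after seeing the data, single barcode sets, other cell minimums, leaving out the deepest cell, another random thinning, and scores without VIM. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.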

Results

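The data are counts of RNA in 603 single SK-N-AS cells. SK-N-AS is a neuroblastoma line, from a tumour of the sympathetic nervous lineage, and is widely used as a line with mesenchymal features. The cells held 1537576 counts in 13641 genes. Totals per cell ran from 1000 to 42404 with a median of 2106, and the median cell had 1179 genes with a count. Barcode set 1 had 316 cells and 786288 counts, and barcode set 2 had 287 cells and 751288 counts. The deepest cell held 2.76% of all counts, and the next deepest had a total of 13400. Ribosomal protein genes took 16.9% of the counts. Because the columns carry no sample, all values describe this pool of cells and have no replicates.

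Outside the ribosomal protein genes, the most abundant transcript was TMSB10, which binds monomeric actin, at 7235 CPM. FTL, the ferritin light chain, followed at 5877 CPM, and the intermediate filament gene VIM at 5649 CPM (5531 to 5769) with a count in 99.3% of cells. GAPDH reached 5537 CPM, the calcium-binding genes S100A6 and S100A4 reached 5303 and 4617 CPM, and the tubulin gene TUBA1B 5149 CPM. GNB2L1, which encodes a ribosome-bound scaffold, stood at 4550.0 CPM, and the glycolytic gene PKM2 at 3163 CPM. FTL, GAPDH and TUBA1B have processed pseudogenes or close paralogs, so how reads were shared among copies is uncertain.

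The first comparison asks where these cells stand between the mesenchymal and the adrenergic state, the 2 transcriptional identities known in neuroblastoma lines. The mesenchymal genes were well expressed. VIM led, the BMP target ID1 stood at 835 CPM (790.0 to 882), the receptor tyrosine kinase AXL at 406 CPM (375 to 439) with a count in 50.1% of cells, and the hyaluronan receptor CD44 at 235 CPM (212 to 261). The AP-1 gene FOSL1 reached 233 CPM, TEAD1 194 CPM and TWIST1 119 CPM. MAFF, MEOX1, MEOX2, NOTCH2 and SIX4 had 0 counts, which allows up to 1.95 CPM each.

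Several regulators of the adrenergic state were expressed as well. TBX2 reached 407 CPM (376 to 440.3) with a count in 53.1% of cells, HAND2 273 CPM (248 to 301), GATA2 202 CPM (180 to 225) and GATA3 169 CPM. The enzymes of noradrenaline synthesis split. DDC, the decarboxylase, stood at 194 CPM (172 to 217), while TH, the first enzyme of the path, had 3 counts (1.95 CPM, 0.402 to 5.70) and DBH, the last, had 0. ZNF536 was also at 0. The median level of the mesenchymal list was 5.17 on the log2 scale and that of the adrenergic list 3.78, a difference of 1.39 (0.88 to 1.65). Within barcode sets 1 and 2 the difference was 1.29 and 1.29. The mesenchymal median lay at percentile 99.995 of random lists and the adrenergic median at 91.2. VIM alone made up 66.9% of the mesenchymal list's counts, and with only members of at least 5 CPM, 27 mesenchymal and 17 adrenergic, the difference was 0.47, so its size depends on the members below that level.

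**Figure D1:**
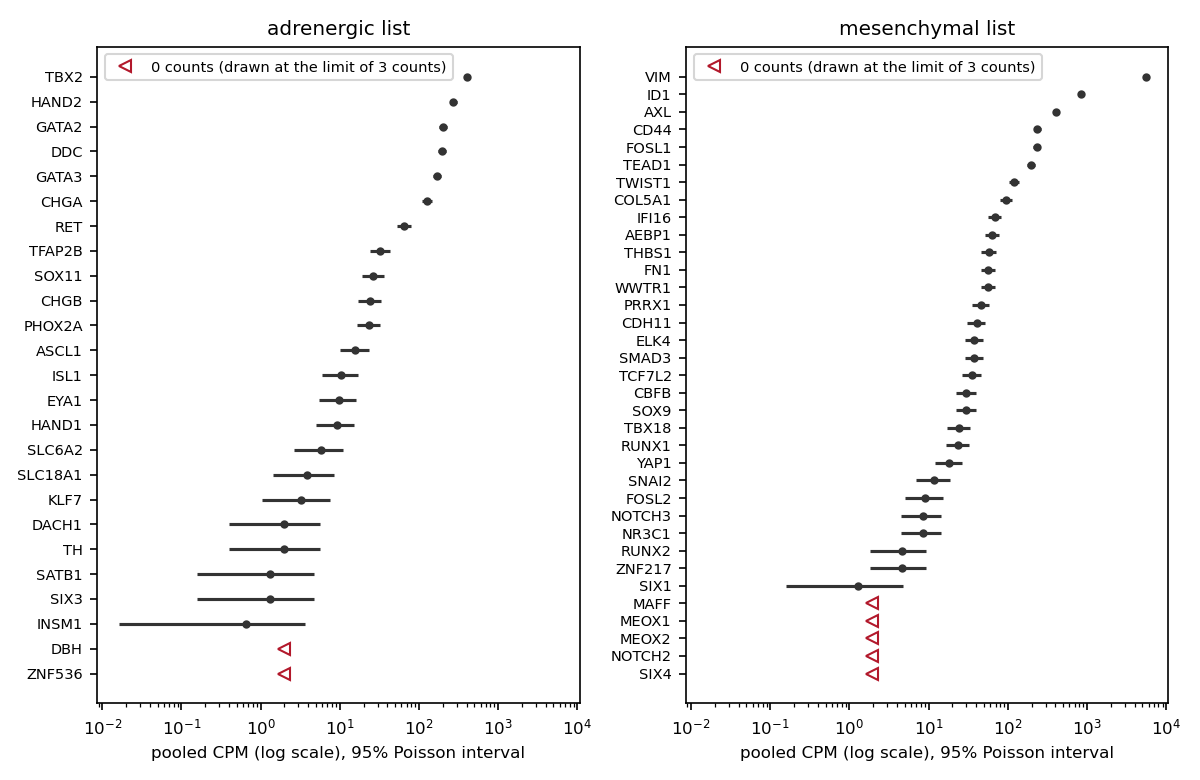
Pooled CPM on a log axis of members of the adrenergic and mesenchymal lists in 603 SK-N-AS cells, with exact 95% Poisson intervals as bars. VIM at 5649 CPM stands far above the rest, and TBX2 and AXL, the leading adrenergic transcription factor and a mesenchymal receptor, lie at 407 and 406 CPM.

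Among genes of the sympathetic lineage, SCG2, a granin of secretory vesicles, reached 797 CPM with a count in 70.8% of cells. TUBB3 stood at 246 CPM, PRPH at 102 CPM and STMN2 at 35.8 CPM, and the median of the sympathetic neuroblast list was 3.07 (percentile 69.6). The granin CHGA stood at 126 CPM but had a count in 5.47% of cells only, and the chromaffin list had a median of 2.29 (percentile 46.3). Genes usual in fibroblasts were present, with COL1A1 at 301 CPM, LUM at 135 CPM, DCN at 114 CPM and COL3A1 with 156 counts, and a list median of 4.31 (percentile 91.6). COL1A2, whose chain normally pairs with that of COL1A1, had 0 counts, as did TCF21. KRT18 reached 334 CPM in an epithelial list with a median of 2.72.

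Markers of other tissues were nearly absent. Medians were 0 for the Schwann cell precursor, adrenal cortex, endothelial, immune and erythroid lists, with 12 of 15, 9 of 10, 6 of 10, 7 of 13 and 7 of 7 members at 0 counts. Their highest members were ITGA4 (7.15 CPM), FDX1 (21.5 CPM), FLT1 (25.4 CPM) and CD68 (54.6 CPM), and the pan-leukocyte gene PTPRC had 18.9 CPM. SOX10, the factor that marks Schwann cell precursors, had 0 counts.

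Oncogenes of neuroblastoma were low. MYCN had 8 counts, an interval of 2.25 to 10.3 CPM, and MYC 11 counts (7.15 CPM, 3.57 to 12.8), while their partner MAX stood at 48.8 CPM. The MYC family list had a median of 3.03 (percentile 64.0). ALK, LIN28B, NTRK2 and TERT had 0 counts, NRAS had 68.3 CPM and the surface antigen CD276 76.7 CPM, in a list of neuroblastoma loci with a median of 3.24 (percentile 75.4). Transcription factors with short-lived mRNA are thinly sampled at this depth, so low counts of MYC and MYCN say little about single cells.

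Genes of respiration, the cytoskeleton, protein folding and chromatin had the highest levels of the programs. The list of respiratory chain genes had a median log2 level of 9.48, led by UQCRH at 2955 CPM. The cytoskeleton list had 9.04, the heat shock list 8.21 with HSP90AB1 at 2456 CPM, and the histone list 7.09 with HIST1H4C at 2856 CPM. The G2/M list, genes of mitosis, had 5.94, with HMGB2 at 1454 CPM, TUBB4B at 1052 CPM, BIRC5 at 432 CPM and UBE2C at 331 CPM. The G1/S list, genes of DNA replication, had 5.39, with NASP at 349 CPM, TYMS at 276 CPM, MCM7 at 263 CPM and PCNA at 194 CPM. All 6 of these lists lay at percentile 99.99 of random lists or above.

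Matrix genes were also high. The list of extracellular matrix and epithelial-mesenchymal transition genes had a median of 6.68, with SPARC at 1649 CPM and TIMP1 at 983 CPM. Cholesterol synthesis genes stood at 5.87 (FDPS 401 CPM), targets of MAPK signalling at 5.64 (PHLDA1 304 CPM, ETV4 178 CPM), interferon and MHC class I genes at 5.36 (B2M 359 CPM), genes of the unfolded protein and integrated stress responses at 5.32 (HSPA5 160.0 CPM), and glycolysis and hypoxia genes at 5.02 (ENO1 1270 CPM, with CA9 at 0). Targets of YAP stood lower at 4.26, where CTGF had 0 counts and CYR61 44.9 CPM. The p53 targets stood at 4.14 (CDKN1A 112 CPM) and the immediate early genes at 3.14, where IER3 reached 578 CPM and FOS had 8 counts. In all, 13 of the 28 lists lay above the middle 95% of random lists, which hold many silent genes.

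**Figure D2:**
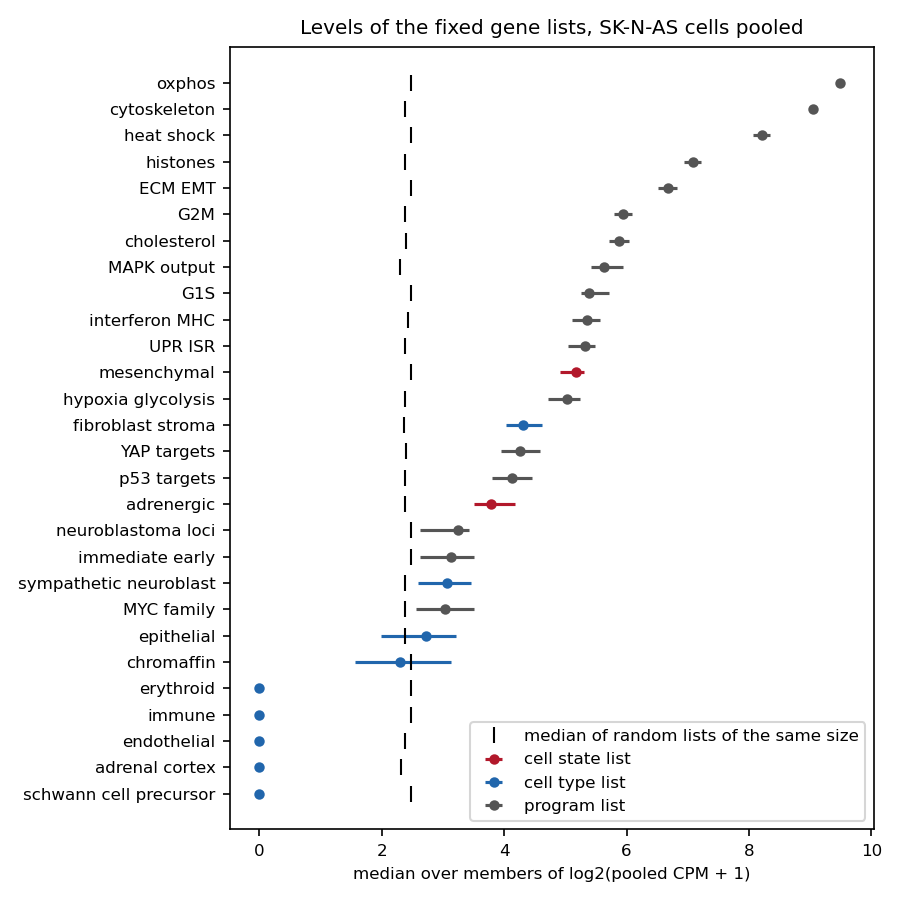
Median over members of log2(pooled CPM + 1) for each fixed gene list, with the interval from Poisson redraws and the median of random lists of the same size as a tick. Respiratory chain (9.48) and cytoskeleton (9.04) genes are highest, the mesenchymal list (5.17) lies above the adrenergic (3.78), and 5 lists of other tissues lie at 0.

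How many cells carried mitotic transcripts was measured at an equal depth of 1100 counts per cell. Of 560 cells, 345 had at least 5 counts of G2/M genes, a share of 61.6% (57.4 to 65.7). The share was 59.3% in barcode set 1 and 64.3% in barcode set 2, and 76.8% of all cells without thinning. The median cell had 6 such counts and the highest had 30, while 34 cells had 0. HMGB2 and TUBB4B gave 19.8% and 14.3% of the list's counts, and HMGB2 had a count in 77.4% of cells. The share and the G2/M score thus rest in part on these genes. The distribution has no gap, and 115 cells lay within 1 count of the threshold, so the share describes a range and not a class of dividing cells.

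Cells with many mitotic transcripts were compared with cells with few, to see which other genes go with division. Among the genes named as higher, the kinase gene PLK1 was higher by a log2 ratio of 4.05 (3.18 to 5.07), PRC1, which bundles midzone microtubules, by 3.70 (2.73 to 4.86), the kinetochore gene SPC25 by 3.53 and the kinesin gene KIF20A by 3.20. The cyclin gene CCNF was higher by 4.59 (2.67 to 7.67, 56 counts against 2), MND1 by 4.54 (1.94 to 9.89, 27 counts against 1), ESPL1, which encodes separase, by 3.54 (1.54 to 6.65, 27 against 2), and SPAG5 by 3.59. The nuclear noncoding RNA MALAT1 was higher by 3.61 (3.04 to 4.25). The other genes named on this side were SHCBP1, KIF4A, C9orf140, ARL6IP1, PBK and FAM83D, the last with the smallest ratio, 2.62.

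Histone genes went with division too. Their summed log2 ratio was 1.13 (1.04 to 1.22), with H2AFX at 2.20 and HIST1H4C at 1.34, while HIST1H2BK went the other way at -0.86. The G1/S list was higher by 0.55 (0.44 to 0.67), with RRM2 at 2.21 and TYMS at 1.49, and of its 27 members of at least 50 counts 20 lay above 0, 12 of them beyond counting. The cytoskeleton list was higher by 0.30 (TUBA1B 0.82) and the heat shock list by 0.28 (HSP90AA1 0.73). Medians per cell at equal depth were 6 histone counts against 2, 3 G1/S counts against 2, and 29.5 cytoskeleton counts against 23.

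Among the genes named as lower where mitotic genes were high, GNG8 had a log2 ratio of -2.49, HERPUD1, a gene of the endoplasmic reticulum stress response, -2.44 (-4.00 to -1.14), the autophagy gene WIPI1 -2.26, CHGA -1.86 and the stress kinase-like gene TRIB3 -1.76. FCGRT, METTL7A, ST20, FAM214B and CDH11 were the others named, the last at -1.75. Most CHGA counts (83.9%) lay in 10 cells, so its ratio hangs on which group a few cells fell in. It was -3.38 in set 1 and -1.54 in set 2. The adrenergic list was lower at -0.36 (-0.51 to -0.22), or -0.30 (-0.45 to -0.16) without CHGA, and all 9 members of at least 50 counts lay below 0, 3 of them beyond counting. The chromaffin list, which shares CHGA and DDC with the adrenergic list, was lower at -0.50 (-0.67 to -0.34). The epithelial list was lower at -0.46, but stood at -1.12 in set 1 and 0.44 in set 2. SPARC was lower at -0.72 and the respiratory chain list at -0.20. A cluster of cells lying in blocks of columns, described below, had more respiratory chain counts (0.20) and fewer G2/M ones (-0.25). Part of the respiratory chain difference can therefore be technical. The unfolded protein list was lower at -0.27, but stood at -0.088 (-0.32 to 0.14) without HERPUD1 and TRIB3. The 25 named genes had the same sign in both barcode sets, save MND1, which had no ratio in set 1. Picking genes by the pooled ratio makes that agreement likely. The compared cells had median totals of 2496 and 2057, and 22 and 33 of them lay at the score that bounds each group. With another random thinning 17 of the 25 genes were named again, and the G1/S ratio was 0.20 with cells split at the median, 0.37 at a lower thinned depth and 0.35 in barcode set 2 alone.

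Cells rich in G1/S transcripts were compared with cells poor in them in the same way, as a reading of DNA replication. Among the genes named as higher, HIST2H2AC stood at a log2 ratio of 2.35 (1.16 to 3.76), BRCA1 at 2.34 (1.29 to 3.55), MCM10 at 2.23, the histone chaperone gene ASF1B at 2.21, the licensing factor gene CDT1 at 2.14, the linker histone gene HIST1H1E at 2.05, GINS1 at 2.04, E2F1, the factor that drives S phase entry, at 1.92, and the DNA ligase gene LIG1 at 1.90. NFX1, NCAPD3, ACD, IDH2, PRPS1 and SKA3 were the others, at 1.68 or above. The histone list was higher by 1.13 (1.04 to 1.21), led by HIST1H4C at 1.62, and all 9 members of at least 50 counts lay above 0, though HIST1H2BK at 0.41 (-0.087 to 0.90) and H1FX at 0.36 (-0.062 to 0.80) did not do so beyond counting. The G2/M list was higher by 0.23 (0.16 to 0.30) and the cholesterol list by 0.33, with IDI1 at 0.50.

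Among the genes named as lower where replication genes were high, CHGA stood at -2.50 (-3.27 to -1.81), OLFML2A at -2.43, APOE at -1.89, the matrix proteoglycan gene VCAN at -1.85, SEMA3C at -1.82, and the nuclear noncoding RNAs NEAT1 and MALAT1 at -2.34 and -1.79 (-2.23 to -1.37). MALAT1 was thus high with mitotic genes and low with replication genes. TLE4, CDCP1 and DNMBP were also lower, at -1.66 or below. Since 10 cells held 83.9% of the CHGA counts, its ratio hangs on which group a few cells fell in, which its interval does not cover. It was -4.22 in set 1 and -1.72 in set 2. The interferon and MHC list was lower at -0.23 (-0.35 to -0.11). Other lists were lower through few genes or depended on which were kept. YAP targets went from -0.38 to -0.20 (-0.46 to 0.054) without AXL (-0.62), and MAPK targets from -0.19 to -0.068 (-0.25 to 0.12) without PHLDA1 (-0.65), though DUSP4 was lower too at -1.04. Adrenergic genes went from -0.25 to -0.097 (-0.24 to 0.048) without CHGA, but to -0.16 (-0.33 to -0.0023) without CHGA, RET and DDC. Medians per cell at equal depth were 9 histone counts against 3 and 7 G2/M counts against 4. The score is thin, with 4 counts or more in the upper group and 2 or fewer in the lower, and 58 and 83 cells at those bounds. Only 7 of the 25 named genes were named again with another random thinning. When the same groups were split by barcode set the 25 kept their sign in both, which picking by the pooled ratio makes likely, though APOE was at -0.38 in set 2. Under alternatives 4 of them reversed, SEMA3C with groups made within set 2 alone, APOE at the lower thinned depth (1.17), and NFX1 (-0.13) and NEAT1 (0.15) with a minimum of 1500 counts.

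The last score comparison asks what goes with the mesenchymal list within the line. MAPK targets were higher with it, by a log2 ratio of 0.47 (0.29 to 0.64), and all 9 members of at least 50 counts lay above 0. Only SPRY2, a feedback inhibitor of receptor signalling, at 1.03, PHLDA1 at 0.50 and ETV4 at 0.49 did so beyond counting. The matrix list without shared genes was higher by 0.25 (0.17 to 0.33), or 0.19 (0.11 to 0.28) without COL1A1, with COL1A1 at 1.09 and CDH2 at 0.55 while SPARC was lower at -0.24. Immediate early genes were higher by 0.26, but by 0.057 (-0.24 to 0.36) without IER3 (0.39), and YAP targets by 0.26, but by 0.20 (-0.045 to 0.45) without CYR61 (0.86). The fibroblast list was higher by 0.40, and without COL1A1 it stood at -0.10. The cell cycle lists hardly differed, G2/M at -0.04 (-0.11 to 0.02) and G1/S at -0.02.

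Among the genes named as lower, GCG, the glucagon gene, had a log2 ratio of -3.00 (-3.92 to -2.19), SHD -2.72, the joint row of INS-IGF2 and INS -2.26 (-2.53 to -1.99), the nicotinic receptor gene CHRNA3 -2.14, CHGA -1.58 and the receptor gene RET -1.53. TMEM108, PARP2, SLIT3 and TMEM176B were also lower. Few cells held much of some of these genes, with 83.9% of CHGA, 59.5% of GCG and 48.8% of INS-IGF2 counts in 10 cells each. The ratios of these genes hang on which group a few cells fell in, which their intervals do not cover. The chromaffin list stood at -0.095 (-0.25 to 0.066), and at -0.32 (-0.60 to -0.049) without SCG2. The adrenergic list was lower at -0.19 (-0.33 to -0.05), but stood at -0.11 (-0.25 to 0.042) without CHGA and at 0.023 (-0.14 to 0.18) without CHGA, RET and DDC (-0.61), so the difference lay in those genes. Of its regulators, TBX2 at -0.02, HAND2 at 0.16, GATA2 at -0.06 and GATA3 at -0.08 hardly differed. The sympathetic neuroblast list was higher by 0.23 (0.03 to 0.43) through TUBB3 (0.65), and stood at 0.024 (-0.22 to 0.27) without it. The respiratory chain list was lower at -0.24, and at -0.22 without NDUFA4 (-0.85). NDUFA4 is a leading gene of a cluster whose cells lie in blocks of columns, which had more respiratory chain counts (0.20) and fewer mesenchymal ones (-0.13), so part of this difference can be technical. Genes named as higher were FADD (1.86), ANXA7, MT1E (1.80), DDX31, the hypoxia factor gene EPAS1 (1.66), ARHGEF1, ARHGDIB, ACAT1, POLM, PMM1, SIRPA, SCAMP2, MFSD10, INTS4 and MYO19 (1.34). When the same groups were split by barcode set, all 25 kept their sign in both, which picking by the pooled ratio makes likely. With groups made within set 2 alone PMM1 and PARP2 reversed and the adrenergic ratio was -0.59. VIM sets most of this score, and without it the adrenergic ratio was -0.40, ARHGDIB reversed (-0.46) and 9 of the 25 genes were named again. Without the deepest cell the adrenergic ratio was -0.36, another thinning named 8 of the 25 genes again, and 33 and 62 cells lay at the scores that bound the groups.

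**Figure D3:**
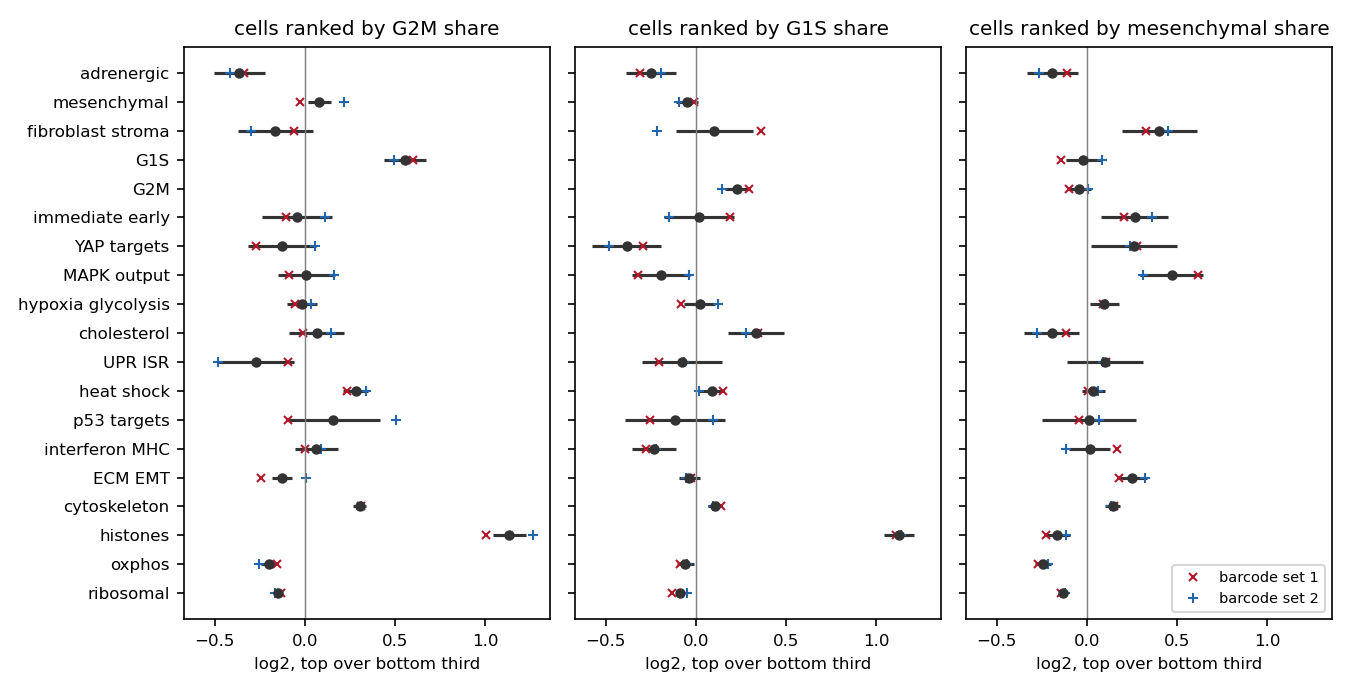
Log2 ratio of summed CPM of selected gene lists, with 95% conditional intervals. The 186 cells with the highest share of G2/M, G1/S or mesenchymal genes are set against the 186 with the lowest. Histone genes go with both cell cycle scores (1.13 and 1.13). Among the lists drawn, the adrenergic list lies furthest below 0 in the G2/M comparison (-0.36). The chromaffin (-0.50) and epithelial (-0.46) lists, lower still there, are not drawn.

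Whether the genes of a list rise and fall together from cell to cell was measured by their mean pairwise rho. G2/M genes had the highest mean, 0.0688, followed by adrenergic genes at 0.0666, chromaffin genes at 0.0661 and histone genes at 0.0632. Within barcode sets 1 and 2 the adrenergic value was 0.0656 and 0.0667. The strongest adrenergic pairs were CHGA with RET at 0.262, DDC with RET at 0.244, DDC with CHGA at 0.193 and GATA2 with DDC at 0.166. Fibroblast genes had 0.0464 (DCN with LUM 0.156), unfolded protein genes 0.0357, interferon and MHC genes 0.0345, cytoskeleton genes 0.0331 and G1/S genes 0.0303. Mesenchymal genes were weakly tied at 0.0172, with VIM and CD44 at 0.151. Immediate early genes were not tied, at -0.0138, and sympathetic neuroblast genes little, at 0.0122. Of 21 lists with enough members, 15 lay above the middle 95% of random lists matched on mean.

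Over 136 pairs of lists the median size of r was 0.0538, and 4 pairs passed 0.2 in size. G1/S and histone scores rose together (r 0.376, rho 0.468, with r 0.426 and 0.316 in sets 1 and 2), as did G2/M and cytoskeleton scores (r 0.243, rho 0.286, with 0.243 and 0.255). G2/M and histone scores were tied more by rank (r 0.194, rho 0.392, with rho 0.352 and 0.431), and G2/M and heat shock scores less (r 0.195, rho 0.216). Respiratory chain scores fell with cytoskeleton scores (r -0.236, rho -0.215, with -0.240 and -0.214) and with mesenchymal scores (r -0.227, rho -0.224, with -0.246 and -0.207). The last value was -0.0730 without VIM, and -0.219 given the share of the genes that lead the cluster lying in blocks of columns. Mesenchymal and adrenergic scores were little correlated (r -0.0567, rho -0.0547, with -0.0381 and -0.0746), as were G2/M and G1/S scores by r (0.0540, rho 0.20). The adrenergic score had a median of 1 count per cell in both mesenchymal groups, and VIM sets most of the mesenchymal score. A small r between these 2 scores therefore does not show that the states are independent. Shares of a fixed total compete for the same counts, and cells are not independent replicates, so no p-value is given.

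Strong cell-to-cell variation was seen in few genes. Over 2067 genes the median Fano factor was 1.09, against 0.995 for simulated genes without added variation, and 33 genes (1.60%) passed 2. The joint row of INS-IGF2 and INS had the most, a Fano factor of 13.5, with counts in 23.1% of cells and 48.8% of its counts in 10 cells. This row is a readthrough locus overlapping INS and IGF2, and which transcript gave the counts cannot be read from it. CHGA followed with a Fano factor of 7.38 and 83.9% of its counts in 10 cells. Other secreted products were on the list, the chemokine gene CCL2 (3.69), GCG (3.56), the neuropeptide genes VIP (3.49) and NPY (2.34), COL1A1 (2.67) and the plasminogen activator gene PLAT (2.57), together with DDC (2.72). MALAT1 had 5.31 and HIST1H4C 5.19. Abundant genes made up the rest, FTL (7.33), MTRNR2L1 (3.45), S100A6, RPL35A, VIM (3.11), ACTB, MIF, S100A4 and RPS29. MTRNR2L1 is nearly identical to part of a mitochondrial ribosomal RNA, so its reads are of uncertain source.

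**Figure D4:**
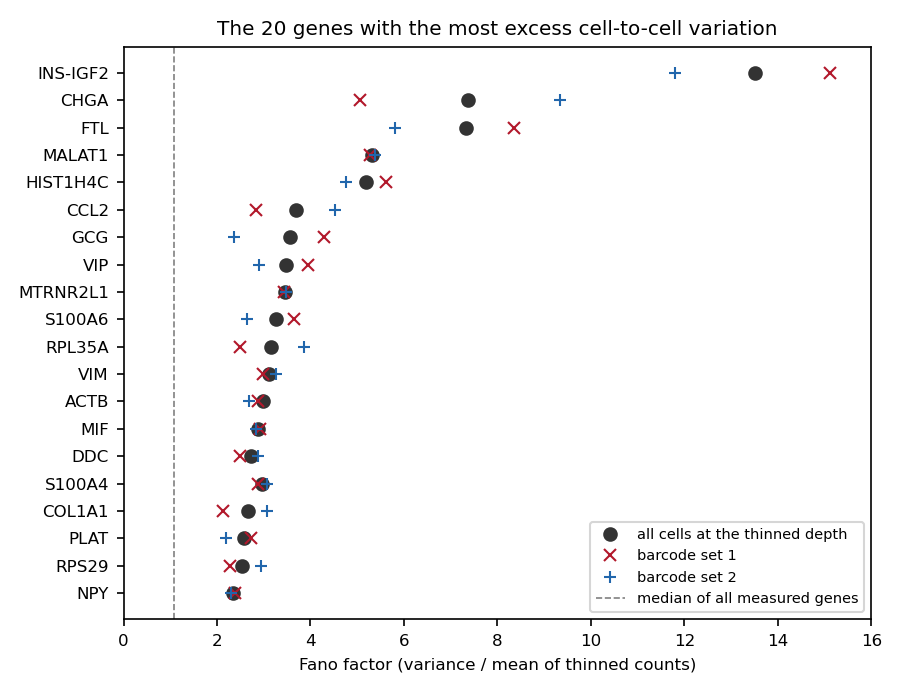
Fano factor of thinned counts across 560 cells for the 20 genes with the most variation beyond that of genes of like mean, with the median of all measured genes (1.09) as a dashed line. The joint row of INS-IGF2 and INS (13.5), CHGA (7.38) and FTL (7.33) stand out.

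Clustering gave 3 groups of 270, 189 and 144 cells, or 44.8% (40.8 to 48.8), 31.3% (27.7 to 35.2) and 23.9% (20.5 to 27.5). None had 3 leading markers of a cell type, so all stay unnamed. The smallest had 2 markers among its 10 leading genes, CHGA and DDC, each on both the adrenergic and the chromaffin list. The groups took 39.6%, 41.5% and 19.0% of barcode set 1 and 50.5%, 20.2% and 29.3% of barcode set 2. Simulated cells of 1 kind also split into 2 clusters, so the number of groups is not evidence of types.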

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

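The alternatives with single barcode sets, a minimum of 1500 counts, no deepest cell, no VIM, another thinning, an adjustment for the cluster whose cells lie side by side or, in the score comparisons, per-cell CPM were chosen after seeing the data, and the rest before. Of 142 values of the main results under an alternative, 124 stayed within their counting interval or limit, 18 moved beyond it and 0 reversed. Here and among the named genes, a minimum of 1000 counts or no minimum keeps every cell. Those values stay the same by construction and add no evidence. Reversal was not defined for results that are counts or shares, or for correlations under 0.1 in size. The cause was not tested for any change unless said.

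The mesenchymal minus adrenergic difference fell from 1.39 to 0.71 as a mean over members and to 0.47 over members of at least 5 CPM, where low members of both lists drop out. The G1/S ratio in the G2/M comparison (0.55) was 0.20 with cells split at the median, 0.68 with narrower groups, 0.37 at a lower thinned depth, 0.35 in barcode set 2 and 0.43 with a minimum of 1500 counts. The G2/M ratio in the G1/S comparison (0.23) was 0.35 in barcode set 1 and 0.37 with that minimum. The adrenergic ratio in the mesenchymal comparison (-0.19) was -0.39 with narrower groups, -0.59 in barcode set 2, -0.36 without the deepest cell and -0.40 without VIM.

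Single genes that reversed were APOE (1.17 at the lower depth), SEMA3C (0.29 in set 2), NFX1 (-0.13) and NEAT1 (0.15, both with the minimum of 1500) in the G1/S comparison, and PMM1 (-0.089) and PARP2 (1.59, both in set 2) and ARHGDIB (-0.46 without VIM) in the mesenchymal one. Of 247, 250 and 275 values of named genes in the G2/M, G1/S and mesenchymal comparisons, 221, 213 and 237 stayed within their interval.

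The mitotic share (61.6%) was 77.3% at a threshold of 3 counts, 32.3% at 10 and 35.0% at the lower depth, by construction. The r of mesenchymal and respiratory chain scores was -0.0730 without VIM. Resolution 1 gave 8 clusters. List levels stayed within their interval in 146 of 168 values and covariation in 105 of 120.

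Depth limits genes under 1.95 CPM, and the G1/S score most among the scores. Normalization by edgeR and DESeq2, another tool and leaving out samples were not run, since no sample is known, and minimums of 500 and 1000 counts remove no cell. No paired analysis was possible because the columns carry no sample.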

Other observations

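All tests in this part were chosen after the result was seen, save the test of deep cells behind CHGA and INS-IGF2. The genes named here as measured across barcode sets were chosen after their values were seen.

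A group of transcripts led by INS-IGF2 marks some of these cells. To measure it on cells that did not define it, each barcode set was clustered alone, and the 10 leading genes of its cluster with the highest DDC share were counted in the other set, with INS-IGF2, C7, PTN, D4S234E and BEX1 shared by both lists. In barcode set 1, 45 of 297 cells (15.2%, 11.3 to 19.7) had at least 5 such counts and 221 had at most 1. In barcode set 2, with the other list, 92 of 263 cells (35.0%, 29.2 to 41.1) had at least 5 and 54 at most 1. The list counted in set 2 also holds HIST1H2BK, SNRPD3 and MIF, which had a count in 91.5% of cells and a thinned mean of 1.91. Cells had a mean of 5.51 listed counts in set 2, against 2.13 in set 1. The upper and lower cells of set 2 can thus differ partly by MIF. Neither its share nor the ratios that follow measure the same contrast as in set 1. The genes rose together in cells that had not defined them, with a mean rho of 0.149 and 0.221, above all 10000 random lists in both.

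Without DDC and CHGA, cells with many of these counts had more of the adrenergic list, by a log2 ratio of 0.72 in set 1 and 0.66 in set 2, and more of the sympathetic neuroblast list, by 0.40 and 0.77. Without DCN, a counted gene in set 1, the fibroblast list stood at 0.16 (-0.22 to 0.53) in set 1 and 0.79 (0.44 to 1.15) in set 2, and COL1A1 at 0.30 (-0.24 to 0.81) and 1.67. The epithelial list was lower at -1.75 and -0.78, with KRT18 at -2.10 and -0.76. RET was higher by 2.38 and 2.87, GCG by 3.68 and 5.51 (2.97 to 10.8, 1 count in the lower cells), VIP by 1.10 and 1.63, GATA2 by 1.69 and 0.97 and GATA3 by 1.18 and 1.14. HAND2 (0.36 and 0.03) differed little, and TBX2 was lower in set 1 at -0.90, and at -0.28 (-0.75 to 0.18) in set 2. Single genes that were lower included AXL at -3.04 and -1.63, PLAT at -2.74 and -2.48, CD44 at -1.71 and -1.09 and FOSL1 at -1.27 and -1.05. The YAP target list was lower at -1.74 and -1.37, and the interferon and MHC list at -1.17 and -0.70. FLT1, a receptor for VEGF, was higher by 2.82 in set 1 and had 15 counts against 0 in set 2. The mesenchymal and matrix lists were slightly lower in set 1, at -0.21 and -0.16, and did not differ beyond counting in set 2, at 0.08 and -0.03. Both lists hold VIM, which was lower in set 1 at -0.18 and higher in set 2 at 0.23. VIM gave 568 of the 853 mesenchymal counts in the upper cells of set 1 and 1343 of 1894 in set 2. The list values thus mostly follow VIM and say little of the other members. Mitotic genes were slightly lower, at -0.16 and -0.16.

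The first pattern weighed is that cells with INS-IGF2, CHGA, DDC and NPY counts are set apart from the rest. Position within a barcode set is argued against by neighbouring columns both in the group, 1.06 times as many as random placement gives and within the 0.753 to 1.23 of random orders. A difference between the barcode sets, which would leave no such group inside a set, is argued against by a mean rho of at least 0.149 within each set, though the unequal shares of 19.0% and 29.3% stay open. Depth is argued against by a rho of -0.0120 between the group genes' share and the cell's total. The group's median total was 2202, against 2031 and 2194 in the other clusters. Doublets are not settled by this rho, since mixing with an ordinary cell would lower the share. Cells of another line or type cannot be told apart from a state of SK-N-AS, which may hold part of the adrenergic list but less AXL, because 12 of the 200 genes with the most counts were over 2-fold apart, against 2 and 4 in the other clusters.

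The second pattern is that RPS29, RPL26, NDUFA4 and SLIRP counts were higher in 1 cluster of cells. Neighbouring columns both in this cluster were 1.46 times as many as random placement gives, against 0.836 to 1.14 in random orders, which is what a library pool or plate position would give. The pattern's 61 genes were picked for a log2 of at least 1 in this cluster, which sets their median of 1.36. Pseudogene reads raising ribosomal protein genes as a set are argued against by that set's median log2 of 0.066. Yet 9 of its 71 genes were among the 61, so pseudogene reads at those genes stay open. GC content as the only cause is argued against, since genes of like GC did not move as far. The pattern's genes kept a median of 1.49 after their subtraction. A smaller part played by GC stays open, because the 61 genes were picked for their ratio and the genes subtracted were not. Across the genes compared, the rho of GC content with the log2 ratio was -0.136. The pattern may therefore be technical, and no biological explanation was tested.

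The third pattern is that CHGA and INS-IGF2 counts were held by few cells. If amplification copies had been counted as molecules in genes at large, most genes would vary beyond counting, but their median Fano factor was 1.09. This value cannot speak to copies of single genes or in single wells, which were not examined. Deep cells are argued against, since the 10 cells with the most CHGA counts had 1.12 times the median total. Of the 10 cells with the most counts, 9 for CHGA and 9 for INS-IGF2 lay in the group of the first pattern. These genes help define that group. In barcode set 2, where CHGA was not a counted gene, cells with many of the counted transcripts had 81 CHGA counts, against 2 in the lower cells. The third pattern is thus largely the first seen again. Bursts of peptide expression within that group are a candidate explanation, and no group of the design tests it.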
